A study of Mus musculus with 3 samples.

How the data were processed

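Visium spatial transcriptomes of uterine sections at pregnancy day 7.5 were measured in 3 libraries. The values are UMI counts per gene and spot, deposited by the authors as whole numbers without normalization, and written by Space Ranger 1.2.2 per the file headers. The submitters' processing notes name Cell Ranger and mm10. Aligner settings, gene annotation version and the spot filter are not given in the sources used here. Each matrix held 32285 genes, and the 3978 deposited spots were taken as the spots over tissue. Spot positions and section images were not used here. Of the gene IDs, 32158 were found in GENCODE release 21 (GRCm38), which gave coordinates for 500 of 501 named or listed genes.

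Spots with fewer than 1000 UMIs were left out (38, 1 and 0 per library), leaving 3939. The genes were divided at random into 2 sets of 16142 and 16143. Regions were found on the 1500 most variable genes of the first set, excluding the 431 symbols of 35 gene lists, so that no gene both defined a region and was tested in it. Counts were scaled to 10000 per spot, log transformed, centred within each library, divided by the pooled SD and limited to 10. Leiden clustering (resolution 0.6, seed 0) ran on a shared-neighbour graph of 15 neighbours in 20 principal components. No doublet caller was run, since a spot holds several cells. Shares have exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 is given the limit of 3 counts. The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined.

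Counts were summed per library and region for sums of at least 20 spots, and regions with sums in at least 2 libraries were tested, giving 13 regions, 37 sums of 117657 to 6367035 UMIs and 6692 genes after edgeR's filterByExpr. The genes of the second set and the list genes were fitted together with edgeR's quasi-likelihood model (TMM scaling, library as a block), since the regions come from the same libraries. The contrast was a region minus the mean of the other regions on the log2 scale. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over all list and region tests, and again with an estimated correlation. The regions with the highest mean log2 fold change of the decidual list (7) and the natural killer cell list (3) were compared in the same fit without the genes of those lists, and without those lists among the list tests. P-values rest on the spread between 3 libraries of 1 group, pooled over all regions in the fit. The labels speak of biological replicates, and 1 library mixes 2 of them.

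Named genes were, per region and for the direct comparison, drawn from up to 8 called genes with the largest rise and 4 with the largest fall, with the same sign in every library and a mean log2 CPM of at least 3, passing over genes without a symbol name. To these came up to 4 members with the smallest p of each list that passed, and the 2 most counted members of a list for its level. The text gives a selection of them, made while writing, and the values of some list members are not reported here. A fall to 0 counts is given as a bound against 3 counts over the group, and 1 to 3 counts as a ratio with an exact Poisson interval. Both are ratios to the arithmetic mean CPM of the other sums, which a few regions can set. They can thus be far larger than the fitted fold change. The interval covers the region's own count only. List pairs were ranked with Spearman's rho across spots thinned to 3000 UMIs, which left out 206, 3 and 3 spots. The lists covered the decidua, hormone response, matrix, basement membrane, immune cells, vessels, muscle, epithelium, trophoblast, yolk sac, embryo, blood, cell cycle, metabolism and stress.

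Simulated counts held 200 changed genes for the comparison of region 1 (6692 genes). An adjusted p under 0.05 was reached by 28.4% of genes changed by 1.5 times, 88.1% by 2 times and 100% by 4 times. It was reached by 0.139% of unchanged genes. These shares leave out the minimum fold change, so they are not the shares that a call would find. The median log2 fold change in size was 0.60 for 1.5 times and 1.04 for 2 times. In that simulation 1 of 100 random lists had p under 0.05. Its genes were drawn independently of each other and without library differences, so it cannot test the preset correlation. Alternatives were DESeq2 size factors, DESeq2's Wald test, no filter, no minimum fold change, no block, pooled other spots as the reference, clustering on the other gene set, no centring, resolutions of 0.3 and 1.0, no minimum or at least 5000 UMIs per spot, each library left out, and thinning to 1000 UMIs or none. Region labels were also shuffled within libraries. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.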

Results

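Uterine sections of mice at pregnancy day 7.5 were placed on 10x Visium slides, on which each barcoded spot captures the RNA of a small tissue area that can hold several cells. The series held 1 group of 3 libraries, each from 1 capture area, and no treatment. The library of replicates 1 and 2 held sections of 2 biological replicates in 1 matrix and counted as 1 replicate, so n is at most 3. That library had 1811 spots and 16915926 UMIs, with a median of 8038 UMIs and 2738 genes per spot. Replicate 3 had 1081 spots, 27279702 UMIs and medians of 26543 UMIs and 5302 genes. Replicate 4 had 1086 spots, 29953072 UMIs and medians of 28286 UMIs and 5392 genes. The shallower library thus carried the largest counting error. Log2 CPM of 16657 genes correlated across genes at r = 0.983 to 0.990 between libraries, where genes are not independent replicates.

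The series title names the uterine microenvironment of early pregnancy as the subject, so the comparisons were made between tissue regions within the libraries. Spots with at least 1000 UMIs fell into 14 regions, of which 13 were tested. Regions are given by number and by the genes that led the clustering, which were not tested themselves. The largest in mean share was region 1 (Psca, Olr1, Pdzk1ip1), with 13.96% ± 1.11 of spots (SD, n = 3), although region 3 or 4 held more in each library. Region 5 (Scn3b, Vsig2, Efemp1) took 9.48% ± 0.69 and region 6 (Stmn2, Dppa1, Hmgn5) took 8.40% ± 0.48. Region 3 (Spp1, AW112010, Chn1) took 6.94% of spots in the library of replicates 1 and 2 (exact 95% binomial interval 5.80 to 8.22), 18.2% in replicate 3 (16.0 to 20.7) and 13.9% in replicate 4 (11.9 to 16.1). Region 4 (Nppa, Igfbp2, Tnni2) took 15.3%, 5.93% and 5.34% in the same order. Its spots had medians of 3649, 8086 and 14474 UMIs, below the median of each library. With at least 5000 UMIs per spot its best match had a Jaccard index of 0.36. Depth and tissue thus cannot be told apart in its shares. Regions 12 (Bex2, Fabp3, Trap1a) and 13 (Tnnc1, Htra1, Retn) held 1.41% and 1.13% of spots in the library of replicates 1 and 2, and 2.49% and 2.30% in replicate 4. Neither had any of the 1080 spots of replicate 3, where the limit of 3 counts is a share of 0.278% and the exact 95% interval reaches 0.341%. Intervals and floors cover counting error only.

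**Figure D1:**
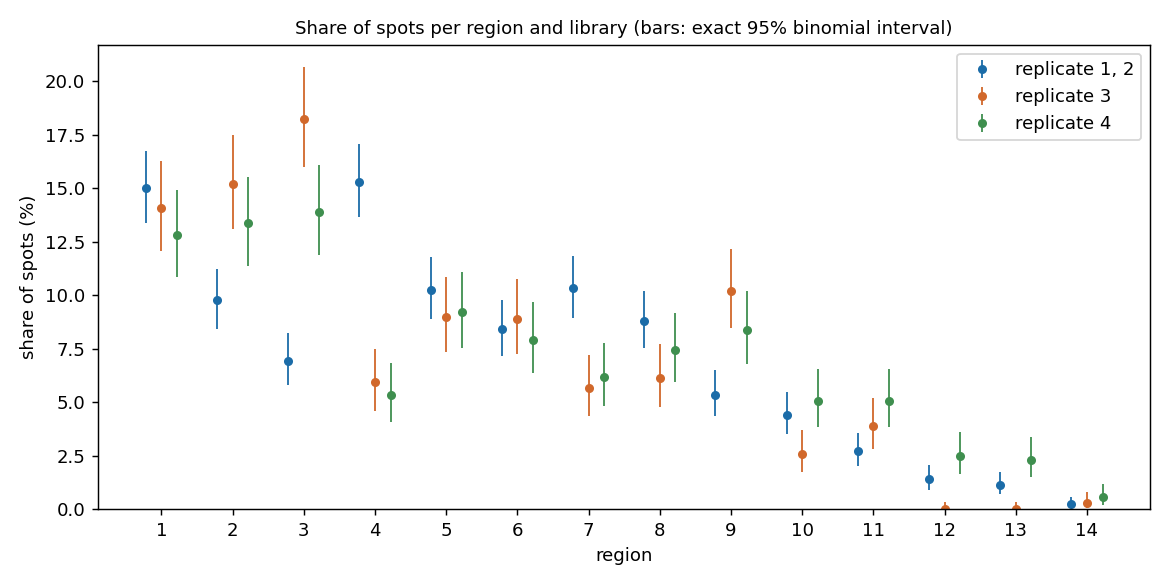
Share of spots (%) in each of the 14 regions, one point per library with its exact 95% binomial interval. Region 3 ranged from 6.94% to 18.2% between libraries, and regions 12 and 13 had no spots in replicate 3.

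Counts were summed per library and region, and each region was tested against the mean log2 level of the other regions with edgeR's quasi-likelihood test, so a region can be above that mean while 1 other region is far higher. Values in parentheses after a gene are log2 fold changes ± SE of the fit, with Benjamini-Hochberg adjusted p under the threshold of 0.05 unless a p is given. Folds with a counting interval or bound are instead ratios to the arithmetic mean CPM of the other sums, on another scale. Regions had sums in 3 libraries (2 for regions 12 and 13). The spread behind each SE is pooled over all 37 sums, so it is not the variation between the libraries of that region alone. CPM of a gene in a region are TMM-scaled where so named, and CPM of lists are per UMIs counted, so the scales cannot be set side by side. Each gene named among the largest changes had the same sign in every library with both sums. Genes called higher and lower numbered 511 and 468 in region 1, 1125 and 435 in region 2, 866 and 456 in region 3, 1030 and 238 in region 4, 645 and 363 in region 5, 635 and 386 in region 6, and 870 and 708 in region 7. They numbered 828 and 188 in region 8, 967 and 368 in region 9, 1134 and 749 in region 10, 883 and 607 in region 11, 966 and 952 in region 12, and 833 and 790 in region 13, each of 6692 genes tested. With relative log expression scaling the split changed to 382 higher and 570 lower in region 1, 703 and 867 in region 7, and 1344 and 538 in region 10. Against the pooled other spots, more genes were lower than higher in 12 of 13 regions, among them 282 higher and 1198 lower in region 1, 256 and 733 in region 5 and 201 and 825 in region 6. DESeq2's Wald test gave 348 and 935 in region 1. Without replicate 4 fewer genes were lower in each of the 13 regions, such as 202 in region 1, 276 in region 7 and 134 in region 9. Which side holds more genes thus depends on the scaling and the reference, and the number of lower genes on replicate 4. Relative log expression scaling moved the median of all genes by -0.16 in regions 1 and 7, 0.12 in region 4 and 0.20 in region 10 (log2). Of 429 tests of the fixed gene lists, 198 passed with the preset correlation and 35 with an estimated correlation. Counts of list members adjusted over the list alone differed in 17 of the 208 tests that passed in the regions and the direct comparison, by at most 2 members, and are given where they differ.

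**Figure D2:**
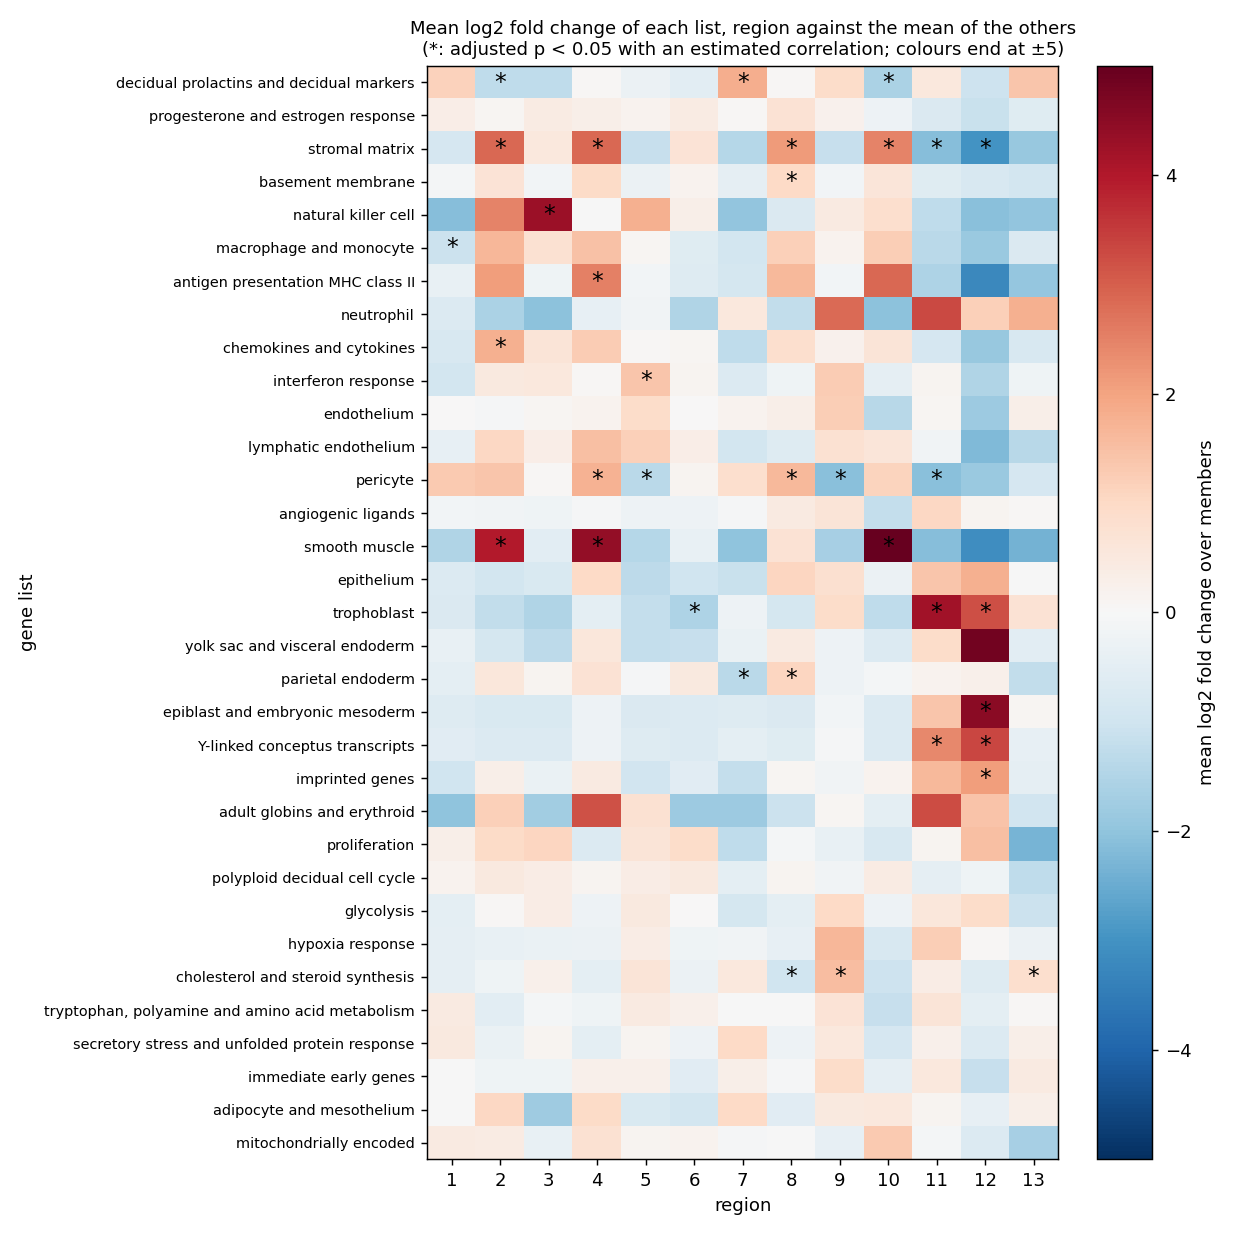
Mean log2 fold change of the members of each gene list (vertical axis) in each tested region (horizontal axis) against the mean of the other regions, with colours ending at ±5. Asterisks mark the 35 tests that passed with an estimated correlation, such as smooth muscle in regions 2, 4 and 10.

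Positions on GRCm38 (mm10), with GENCODE release 21 annotation, are given for the genes followed most closely, all annotated as protein coding and counted over the whole gene: Prl8a2 (ENSMUSG00000018259, chromosome 13, 27345673 to 27354216), Prl3c1 (ENSMUSG00000017922, chromosome 13, 27196659 to 27203749), Prl3d1 (ENSMUSG00000057170, chromosome 13, 27094190 to 27100258), Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), Prf1 (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680), Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), Apoa1 (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772), Prss28 (ENSMUSG00000024171, chromosome 17, 25308646 to 25311876) and Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847).

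Region 1 was led by Coch (4.18 ± 0.12), Mt3 (4.10 ± 0.16), Sprr2h (3.68 ± 0.14), Dio3 (3.38 ± 0.15) and Gatm (3.31 ± 0.12). Dio3 encodes the deiodinase that inactivates thyroid hormone, Gatm the first enzyme of creatine synthesis, and Mt3 a metallothionein. Dio3 stood at 1863 ± 163 TMM-scaled CPM (SD, n = 3) and Gatm at 4405 ± 444 TMM-scaled CPM (SD, n = 3). Among decidual markers 12 of 20 measured members were higher, including Erv3 (2.97 ± 0.15) and Fkbp5 (2.28 ± 0.12), and 3 were lower (adjusted p = 1.8e-05, adjusted p = 0.054 with an estimated correlation). Pericyte genes were higher for 6 of 7, with Rgs5 (1.87 ± 0.15), Abcc9 (2.35 ± 0.25) and Notch3 (1.45 ± 0.17) (adjusted p = 3.6e-04, adjusted p = 0.065 with an estimated correlation). Progesterone and estrogen response genes were higher for 4 of 13, with Hand2 (1.55 ± 0.09) and Pgr (1.07 ± 0.12) (adjusted p = 0.032, adjusted p = 0.15 with an estimated correlation).

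Macrophage and monocyte genes were lower in region 1 for 8 of 15 and none was higher, with Csf1r (-2.37 ± 0.16), Cd68 (-1.79 ± 0.19) and Tyrobp (-1.79 ± 0.24) (adjusted p = 7.7e-07, adjusted p = 0.037 with an estimated correlation). Natural killer cell genes, among them granzymes of cytotoxic granules, were lower for 6 of 19 (5 adjusted over the list alone), with Gzmc (-3.97 ± 0.63), Gzmd (-3.86 ± 0.58) and Il2rb (-3.56 ± 0.53) (adjusted p = 1.5e-09, adjusted p = 0.078 with an estimated correlation). Smooth muscle genes were lower for 9 of 14, with Tagln (-2.90 ± 0.33) and Actg2 (-2.64 ± 0.26) (adjusted p = 2.3e-07, adjusted p = 0.078 with an estimated correlation). Interferon response genes were lower for 8 of 12, with Ifi27l2a (-2.05 ± 0.18) and Isg15 (-1.59 ± 0.21) (adjusted p = 1.3e-04, adjusted p = 0.072 with an estimated correlation).

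Region 2 (Eln, Itih5, Spon2) combined contractile, matrix and chemokine transcripts. Smooth muscle genes were higher for 13 of 14, led by Pcp4 (5.75 ± 0.14), Cnn1 (5.67 ± 0.11), Actg2 (5.54 ± 0.12) and Myh11 (5.48 ± 0.11), where Myh11 encodes smooth muscle myosin heavy chain (adjusted p = 1.4e-16, adjusted p = 0.011 with an estimated correlation). Stromal matrix genes were higher for 16 of 18, with the collagens Col3a1 (4.25 ± 0.12), Col1a2 (4.17 ± 0.08) and Col5a1 (4.02 ± 0.10) (adjusted p = 5.7e-15, adjusted p = 0.0052 with an estimated correlation). Chemokines and cytokines were higher for 10 of 15, with Ccl21a (5.21 ± 0.30), Cxcl12 (4.54 ± 0.15) and Csf1 (3.24 ± 0.22) (adjusted p = 6.0e-05, adjusted p = 0.031 with an estimated correlation). Macrophage genes were higher for 12 of 15, with Mrc1 (4.47 ± 0.25) and C1qa (3.14 ± 0.12) (adjusted p = 3.4e-05, adjusted p = 0.072 with an estimated correlation). MHC class II genes were higher for 6 of 6, with H2-Aa (2.63 ± 0.23) and H2-Eb1 (2.24 ± 0.18) (adjusted p = 2.2e-04, adjusted p = 0.064 with an estimated correlation).

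In region 2 natural killer cell genes were higher for 19 of 19, with Gzmb (3.72 ± 0.26) and Gzmd (3.44 ± 0.28) (adjusted p = 1.0e-07, adjusted p = 0.10 with an estimated correlation). Decidual markers were lower for 10 of 20, with Erv3 (-3.99 ± 0.30), Prl8a2 (-3.91 ± 0.40) and Cryab (-3.03 ± 0.26), whereas the phosphatase gene Alpl (2.29 ± 0.17) was higher (adjusted p = 9.5e-07, adjusted p = 0.033 with an estimated correlation). The protease gene Klk7 (324-fold, counting interval 58.1 to 12786) and the copper transporter gene Atp7b (33.1-fold, counting interval 11.3 to 160.4) were lower than the mean of the other sums by these ratios of counts. Against the pooled other spots of the same library, which include region 3, the granzymes turned, with Gzmb at -0.054 and Gzmd at -0.31.

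Region 3 (Spp1, AW112010, Chn1) held the highest natural killer cell transcripts. All 19 of 19 measured members were higher, led by Prf1 (6.93 ± 0.23), Gzma (6.65 ± 0.22), Gzmg (6.46 ± 0.26), Gzmf (6.34 ± 0.23) and Gzmb (6.20 ± 0.20) (adjusted p = 1.4e-16, adjusted p = 0.031 with an estimated correlation). Prf1 encodes the pore-forming protein of cytotoxic granules. Gzmd reached 3771 ± 1784 TMM-scaled CPM (SD, n = 3) and Prf1 693 ± 275 TMM-scaled CPM (SD, n = 3). Proliferation genes were higher for 10 of 15, with Mki67 (1.77 ± 0.13), Ccnb2 (1.63 ± 0.15) and Top2a (1.46 ± 0.14) (adjusted p = 2.6e-05, adjusted p = 0.14 with an estimated correlation). Gzmd, Gzme, Gzmf and Gzmg are near-identical copies, so the split of reads between them is uncertain.

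Decidual markers were lower in region 3 for 10 of 20, with Erv3 (-4.83 ± 0.30) and Gatm (-3.07 ± 0.22), while Wnt6 (2.50 ± 0.13) and Angpt4 (1.82 ± 0.13) were higher (adjusted p = 1.7e-05, adjusted p = 0.054 with an estimated correlation). Trophoblast genes were lower for 9 of 16, with Prl3d1 (-5.28 ± 0.59), Tfap2c (-3.30 ± 0.37) and Plac1 (-2.76 ± 0.37) (adjusted p = 1.3e-05, adjusted p = 0.072 with an estimated correlation). The exception was Eomes (3.81 ± 0.27), a transcription factor gene of trophoblast that is also used by natural killer cells. Klk7 (507-fold, counting interval 91 to 20030.1) was lower by that ratio of counts, and so were Gdpd2 (-5.54 ± 0.55) and Mt4 (-5.46 ± 0.45) on the fitted scale. Adipocyte and mesothelium genes were lower for 2 of 6, with Fabp4 (-4.20 ± 0.33) and Upk3b (72.2-fold, counting interval 20 to 596) (adjusted p = 0.0025, adjusted p = 0.11 with an estimated correlation).

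Region 4 (Nppa, Igfbp2, Tnni2) carried gland protease, contractile and matrix transcripts. The serine proteases Prss28 (7.16 ± 0.28) and Prss29 (6.80 ± 0.25), made by uterine glands, led the list of named genes, at 624 ± 257 TMM-scaled CPM (SD, n = 3) for Prss28. Smooth muscle genes were higher for 13 of 14, with Cnn1 (6.57 ± 0.11), Tagln (6.06 ± 0.13) and Myh11 (6.0 ± 0.11) (adjusted p = 1.4e-16, adjusted p = 0.011 with an estimated correlation). Stromal matrix genes were higher for 15 of 18, with Col1a2 (4.64 ± 0.08) and Col1a1 (4.08 ± 0.11) (adjusted p = 2.7e-13, adjusted p = 0.0052 with an estimated correlation). Basement membrane genes were higher for 5 of 12, with Hspg2 (2.18 ± 0.10) and Lama4 (2.84 ± 0.14) (adjusted p = 8.0e-04, adjusted p = 0.095 with an estimated correlation). MHC class II genes were higher for 6 of 6, with H2-Aa (3.27 ± 0.26) and H2-Eb1 (3.24 ± 0.19) (adjusted p = 3.4e-05, adjusted p = 0.041 with an estimated correlation). Pericyte genes were higher for 6 of 7, with Cspg4 (2.81 ± 0.19) and Kcnj8 (2.48 ± 0.19) (adjusted p = 9.6e-05, adjusted p = 0.049 with an estimated correlation).

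Adult globin genes were higher in region 4 for 5 of 5, with Hbb-bt (4.38 ± 0.30) and Hba-a1 (4.21 ± 0.31) (adjusted p = 0.0018, adjusted p = 0.27 with an estimated correlation), where each globin shares reads with its near-identical copy. Their summed level varied as much as its mean between libraries, at 13631 ± 13655 CPM (SD, n = 3). The lymph node chemokine gene Ccl21a (7.07 ± 0.28) was higher among chemokines and cytokines, which were higher for 8 of 15 (adjusted p = 0.018, adjusted p = 0.15 with an estimated correlation). Proliferation genes were lower for 3 of 15, with Pcna (-1.27 ± 0.13) and Birc5 (-1.13 ± 0.21) (adjusted p = 2.8e-04, adjusted p = 0.19 with an estimated correlation), and their mean turned to 0.22 (adjusted p = 0.30) at a resolution of 0.3.

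Region 5 (Scn3b, Vsig2, Efemp1) had high interferon response transcripts, though not alone. The list took 1392 ± 346 CPM there, 1422 ± 381 CPM in region 2 and 1144 ± 269 CPM in region 9 (SD, n = 3). Interferon response genes were higher in region 5 for 8 of 12, with Ifit1 (2.55 ± 0.16), Gbp3 (2.24 ± 0.16) and Isg15 (2.22 ± 0.14) (adjusted p = 9.8e-08, adjusted p = 0.019 with an estimated correlation). Endothelial genes were higher for 9 of 17, with the tight junction gene Cldn5 (2.41 ± 0.11) and Emcn (1.71 ± 0.11) and Tie1 (1.39 ± 0.11) (adjusted p = 1.5e-05, adjusted p = 0.080 with an estimated correlation). Pericyte genes were lower for 5 of 7, with Notch3 (-2.55 ± 0.33) and Kcnj8 (-2.12 ± 0.30) (adjusted p = 1.3e-05, adjusted p = 0.031 with an estimated correlation). The receptor gene Qrfpr (4.49 ± 0.17) and the potassium channel gene Kcnd3 (3.76 ± 0.15) led the named genes, and Cxcl12 (-4.28 ± 0.54) and Prl3c1 (-4.18 ± 0.43) were among the lowest.

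Natural killer cell genes were higher in region 5 for 14 of 19 (15 adjusted over the list alone), with Prf1 (3.85 ± 0.32), Gzmg (3.67 ± 0.30) and Gzma (3.54 ± 0.30) (adjusted p = 3.5e-05, adjusted p = 0.19 with an estimated correlation). Gzma stood at 129 ± 47.7 TMM-scaled CPM (SD, n = 3) there against 892 ± 261 TMM-scaled CPM (SD, n = 3) in region 3. Against the pooled other spots of the library the list mean turned to -0.61 (adjusted p = 0.0012), with Prf1 at -0.50, Gzmg at -0.21 and Gzma at -0.54. The call also depended on the clustering, since the list had 0.076 in mean with a downward test (adjusted p = 0.64) in the matching region of the other gene set and -0.21 (adjusted p = 0.26) at a resolution of 1.0. Glycolysis genes were higher for 3 of 16, with Hk2 (1.98 ± 0.19) and Slc2a3 (1.47 ± 0.16) (adjusted p = 0.0031, adjusted p = 0.36 with an estimated correlation).

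Region 6 (Stmn2, Dppa1, Hmgn5) had high Fmo1 (3.96 ± 0.11), Susd2 (3.52 ± 0.11), Sned1 (3.30 ± 0.11), Hsd17b1 (3.37 ± 0.20) and Vcan (3.32 ± 0.15). Hsd17b1 encodes an enzyme that makes estradiol. Decidual markers moved apart, with Wnt6 (3.21 ± 0.13), Tdo2 (2.72 ± 0.14) and Gatm (1.94 ± 0.14) higher among 5 that were, and Prl3c1 (-4.57 ± 0.45), Prl8a2 (-4.03 ± 0.40) and Erv3 (-3.62 ± 0.29) lower among 8 of the 20 (adjusted p = 0.044, adjusted p = 0.31 with an estimated correlation). Proliferation genes were higher for 6 of 15, with Ccna2 (1.34 ± 0.14) and Mki67 (1.19 ± 0.14) (adjusted p = 5.5e-06, adjusted p = 0.11 with an estimated correlation). Trophoblast genes were lower for 9 of 16, with Tfap2c (-3.67 ± 0.44) and Prl3d1 (-3.11 ± 0.53) and Rhox6 (149-fold, counting interval 26.7 to 5887) (adjusted p = 2.6e-07, adjusted p = 0.040 with an estimated correlation). Immediate early genes were lower for 2 of 10, namely Dusp1 (-1.59 ± 0.19) and Egr1 (-3.20 ± 0.61) (adjusted p = 0.013, adjusted p = 0.16 with an estimated correlation), and their mean went to -0.012 with an upward test (adjusted p = 0.89) at a resolution of 0.3.

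Region 7 (Ptx3, Ntn5, Psca) had the highest mean log2 fold change over the decidual list, while region 13 held more Prl8a2 in both libraries that had it (208460 against 182236 and 119823 against 110937 TMM-scaled CPM). Prl3c1 (6.03 ± 0.19), Fabp4 (5.26 ± 0.15), Klk7 (5.04 ± 0.26), Sprr2h (4.98 ± 0.13) and Prl8a2 (4.85 ± 0.20) led the named genes. Prl8a2, a prolactin-family hormone of decidual cells, reached 120398 ± 57692 TMM-scaled CPM (SD, n = 3), and Fabp4, a fatty acid binding protein, 10704 ± 3399.6 TMM-scaled CPM (SD, n = 3). Decidual markers were higher for 14 of 20, with Erv3 (4.75 ± 0.13) and Cryab (4.08 ± 0.14) (adjusted p = 1.6e-06, adjusted p = 0.035 with an estimated correlation). Genes of the secretory stress and unfolded protein response were higher for 7 of 11, with Dnajb9 (2.45 ± 0.10), Xbp1 (1.60 ± 0.10) and Manf (1.51 ± 0.09) (adjusted p = 4.7e-05, adjusted p = 0.086 with an estimated correlation). Reads of the prolactin family can be shared between its closest members.

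Proliferation genes were lower in region 7 for 12 of 15, with Ube2c (-2.37 ± 0.25), Cdk1 (-1.76 ± 0.22) and Mcm5 (-1.5 ± 0.15) (adjusted p = 2.2e-05, adjusted p = 0.14 with an estimated correlation). Rrm2 (2.20 ± 0.10), a subunit of ribonucleotide reductase, was the 1 member that was higher, at 5865 ± 226 TMM-scaled CPM (SD, n = 3). Glycolysis genes were lower for 9 of 16, with Eno1 (-1.81 ± 0.16) and Slc2a1 (-1.65 ± 0.27) (adjusted p = 7.0e-04, adjusted p = 0.30 with an estimated correlation). Genes of the parietal endoderm list were lower for 5 of 10, with Srgn (-2.06 ± 0.19) and Lama1 (-2.85 ± 0.43) (adjusted p = 3.4e-05, adjusted p = 0.0052 with an estimated correlation). That list was highest in regions 5 and 8 (8814 ± 165 and 8468 ± 701 CPM, SD, n = 3). It took 2935 ± 362 CPM in region 11, so it does not stand for parietal endoderm alone. Among macrophage genes Csf1r (1.44 ± 0.11) and Cd68 (1.5 ± 0.14) were higher while C1qa (-2.49 ± 0.37) and Lyz2 (-1.57 ± 0.22) were lower, with 5 of 15 lower in all (adjusted p = 0.014, adjusted p = 0.24 with an estimated correlation). Clustering on the other set of genes turned Csf1r to -0.38 and Cd68 to -0.080.

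Region 8 (Aldh1a2, Mgp, C3) was led by Prss28 (6.20 ± 0.29), Prss29 (6.17 ± 0.26), Sfrp4 (5.49 ± 0.13), Mt4 (5.30 ± 0.17) and Rbp4 (5.25 ± 0.16). Sfrp4 encodes a secreted Wnt antagonist, at 3116 ± 186 TMM-scaled CPM (SD, n = 3). Genes of the stromal matrix were higher for 13 of 18, with Col6a2 (4.12 ± 0.18) and Col1a2 (4.10 ± 0.08) (adjusted p = 2.7e-14, adjusted p = 0.0052 with an estimated correlation). Pericyte genes were higher for 7 of 7, with Cspg4 (2.51 ± 0.17) and Rgs5 (1.86 ± 0.16) (adjusted p = 1.2e-05, adjusted p = 0.031 with an estimated correlation). Basement membrane genes were higher for 6 of 12, with Lama2 (4.51 ± 0.23) and Lamb1 (1.40 ± 0.14) (adjusted p = 2.1e-05, adjusted p = 0.049 with an estimated correlation). Genes of the parietal endoderm list were higher for 6 of 10, with the broadly used matrix and signalling genes Fst (2.44 ± 0.11) and Sparc (1.71 ± 0.08) (adjusted p = 7.2e-05, adjusted p = 0.0076 with an estimated correlation). Cholesterol and steroid synthesis genes were lower for 6 of 11, with Sqle (-2.15 ± 0.24) and Fdps (-1.82 ± 0.17) (adjusted p = 5.3e-06, adjusted p = 0.0052 with an estimated correlation). Smooth muscle genes were higher for 8 of 14 (9 adjusted over the list alone), with Myl9 (1.83 ± 0.16) and Acta2 (1.34 ± 0.17) (adjusted p = 0.016, adjusted p = 0.37 with an estimated correlation), but against the pooled other spots the list mean was -1.48, with Myl9 at -1.06 and Acta2 at -1.46.

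Region 9 (Mrgprg, Pyy, Cyp11b1) was rich in cholesterol and steroid synthesis transcripts, though not alone. In mean CPM that list stood at nearly the same level in region 7, with a difference smaller than the SD of either region. Cholesterol and steroid synthesis genes were higher in region 9 for 10 of 11, with Hsd3b6 (5.02 ± 0.19) and Sqle (2.01 ± 0.12) (adjusted p = 1.3e-05, adjusted p = 0.0052 with an estimated correlation). The steroid 5-alpha reductase gene Srd5a1 (4.38 ± 0.17) reached 2257 ± 1129 TMM-scaled CPM (SD, n = 3). Bco1 (4.43 ± 0.14), a carotenoid cleavage enzyme, and Tfpi (4.01 ± 0.12), an inhibitor of coagulation, were also high. Hypoxia response genes were higher for 7 of 11, with Egln3 (4.68 ± 0.18), Ankrd37 (3.32 ± 0.17), Ndrg1 (2.98 ± 0.12) and Bnip3 (2.27 ± 0.12) (adjusted p = 2.5e-04, adjusted p = 0.054 with an estimated correlation). Glycolysis genes were higher for 6 of 16, with Slc2a3 (2.63 ± 0.14) and Slc16a3 (2.42 ± 0.21) (adjusted p = 1.7e-05, adjusted p = 0.19 with an estimated correlation). Endothelial genes were higher for 14 of 17, with Cldn5 (2.96 ± 0.11) and Cdh5 (2.33 ± 0.12) (adjusted p = 4.7e-06, adjusted p = 0.069 with an estimated correlation), while pericyte genes were lower for 5 of 7, with Notch3 (-3.18 ± 0.39) and Rgs5 (-2.80 ± 0.27) (adjusted p = 1.6e-06, adjusted p = 0.020 with an estimated correlation).

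The calprotectin genes S100a8 (4.13 ± 0.21) and S100a9 (3.97 ± 0.19) were high in region 9, with S100a8 at 5886 ± 605 TMM-scaled CPM (SD, n = 3), within a neutrophil list higher for 5 of 5 (adjusted p = 3.9e-04, adjusted p = 0.086 with an estimated correlation). Its other higher members included Mmp9 (2.90 ± 0.14) and Il1r2 (3.13 ± 0.16), genes that other cell types also use. Interferon response genes were higher for 9 of 12, with Isg15 (2.30 ± 0.15) and Oasl2 (1.99 ± 0.16) (adjusted p = 3.8e-05, adjusted p = 0.054 with an estimated correlation). Immediate early genes were higher for 5 of 10, with Atf3 (2.27 ± 0.19) and Fos (1.45 ± 0.12) (adjusted p = 3.4e-04, adjusted p = 0.064 with an estimated correlation). Decidual markers were higher for 12 of 20, with Prl6a1 (3.83 ± 0.16), Lifr (3.41 ± 0.12) and Prl5a1 (3.06 ± 0.20) (adjusted p = 0.0055, adjusted p = 0.18 with an estimated correlation). Trophoblast genes were higher for 11 of 16 (12 adjusted over the list alone), with Prl3d1 (2.34 ± 0.24) (adjusted p = 0.046, adjusted p = 0.36 with an estimated correlation), but Prl3d1 was at -0.40 and the list mean at -0.36 against the pooled other spots. Thbs4 (126-fold, counting interval 43 to 609) was lower by that ratio of counts.

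Region 10 (Fbxl22, Ppp1r12b, Pcp4l1) had the strongest smooth muscle transcripts. All 14 of 14 members were higher, led by Pcp4 (8.87 ± 0.13), Myh11 (7.93 ± 0.10), Cnn1 (7.72 ± 0.10) and Tagln (7.36 ± 0.12) (adjusted p = 1.4e-16, adjusted p = 0.011 with an estimated correlation), with Acta2 at 8884 ± 1648 TMM-scaled CPM (SD, n = 3). Genes of the stromal matrix were higher for 14 of 18, with Col6a2 (4.65 ± 0.18) and Postn (4.38 ± 0.16) (adjusted p = 8.3e-08, adjusted p = 0.031 with an estimated correlation). MHC class II genes were higher for 6 of 6, with H2-Aa (3.82 ± 0.26) and Cd74 (3.06 ± 0.17) (adjusted p = 1.1e-04, adjusted p = 0.054 with an estimated correlation). Mitochondrially encoded genes were higher for 10 of 12, with mt-Nd3 (1.61 ± 0.14) and mt-Nd4 (1.55 ± 0.12) (adjusted p = 5.5e-06, adjusted p = 0.18 with an estimated correlation). Decidual markers were lower for 14 of 20, with Bmp2 (-2.25 ± 0.25), Angpt4 (-2.42 ± 0.28) and Gatm (-2.02 ± 0.22) (adjusted p = 9.3e-06, adjusted p = 0.049 with an estimated correlation). Endothelial genes were lower for 9 of 17 (10 adjusted over the list alone), with Cdh5 (-3.36 ± 0.31) and Pecam1 (-2.54 ± 0.22) (adjusted p = 2.8e-05, adjusted p = 0.086 with an estimated correlation). Genes of tryptophan, polyamine and amino acid metabolism were lower for 4 of 9 (5 adjusted over the list alone), with Sat1 (-2.12 ± 0.18) and Tdo2 (-1.84 ± 0.23) (adjusted p = 0.0045, adjusted p = 0.056 with an estimated correlation). Sez6l (58.3-fold, counting interval 16.1 to 481) was lower by that ratio of counts.

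Region 11 (Cts7, Plet1, Psg29) carried trophoblast transcripts. Trophoblast genes were higher for 15 of 16, led by Prl4a1 (7.64 ± 0.20), Prl3d1 (7.39 ± 0.16), Hand1 (7.37 ± 0.16) and Plac1 (6.76 ± 0.12) (adjusted p = 1.4e-12, adjusted p = 0.0081 with an estimated correlation). Prl3d1 encodes placental lactogen, the hormone of trophoblast giant cells, and reached 1686 ± 439 TMM-scaled CPM (SD, n = 3). Ceacam15 (7.0 ± 0.15), Prl7a1 (6.82 ± 0.14) and Pfpl (6.61 ± 0.15) were also among the largest rises. The imprinted genes H19 (5.87 ± 0.12), Phlda2 (5.38 ± 0.21), Igf2 (4.58 ± 0.18) and Cdkn1c (4.10 ± 0.19) were higher among 7 of 13 that were (adjusted p = 0.014, adjusted p = 0.18 with an estimated correlation). All 3 of 3 Y-linked genes tested were higher, with Eif2s3y (5.74 ± 0.48) and Ddx3y (5.30 ± 0.60) (adjusted p = 9.6e-05, adjusted p = 0.033 with an estimated correlation). Prl3d1 shares reads with Prl3d2 and Prl3d3.

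The gelatinase gene Mmp9 (6.06 ± 0.11) and the cytokine gene Il15 (3.48 ± 0.27) were high in region 11, and so were the keratins Krt8 (5.16 ± 0.11), Krt7 (4.94 ± 0.17) and Krt18 (4.58 ± 0.20) within an epithelium list higher for 8 of 15 (adjusted p = 0.0067, adjusted p = 0.19 with an estimated correlation). Adult globin genes were higher for 5 of 5, with Hbb-bs (3.36 ± 0.28) and Hba-a1 (3.45 ± 0.31) (adjusted p = 0.0013, adjusted p = 0.26 with an estimated correlation). Hypoxia response genes were higher for 5 of 11, with Adm (5.49 ± 0.14) and Egln3 (4.31 ± 0.23) (adjusted p = 0.0081, adjusted p = 0.13 with an estimated correlation). Genes of the stromal matrix were lower for 14 of 18, with Col1a2 (-3.57 ± 0.16) and Col1a1 (-3.17 ± 0.23) (adjusted p = 9.5e-09, adjusted p = 0.021 with an estimated correlation). Pericyte genes were lower for 5 of 7, with Pdgfrb (-3.40 ± 0.61) and Rgs5 (-2.35 ± 0.31) (adjusted p = 4.5e-05, adjusted p = 0.040 with an estimated correlation). Among macrophage genes Csf1r (2.79 ± 0.10) and Cd68 (1.69 ± 0.15) were higher and C1qa (-3.69 ± 0.46) and C1qc (-3.88 ± 0.62) lower, with 7 of 15 lower in all (adjusted p = 0.0013, adjusted p = 0.14 with an estimated correlation). Ccdc102a (71.3-fold, counting interval 12.8 to 2818) was lower by that ratio of counts.

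Region 12 (Bex2, Fabp3, Trap1a) carried transcripts of the conceptus in the library of replicates 1 and 2 and in replicate 4. Yolk sac and visceral endoderm genes were higher for 15 of 16, with the apolipoprotein genes Apoa1 (7.97 ± 0.21) and Apoc2 (7.44 ± 0.24) and Cubn (7.09 ± 0.24) and Spink1 (4.38 ± 0.32) (adjusted p = 2.4e-12, adjusted p = 0.064 with an estimated correlation). Epiblast and embryonic mesoderm genes were higher for 12 of 12, led by the pluripotency factor Pou5f1 (7.67 ± 0.25) and Mesp1 (7.47 ± 0.41) and Dnmt3b (5.50 ± 0.24) (adjusted p = 4.4e-12, adjusted p = 0.0052 with an estimated correlation). Trophoblast genes were higher for 14 of 16, with Hand1 (5.98 ± 0.31) and Prl3d1 (5.55 ± 0.28) (adjusted p = 1.5e-07, adjusted p = 0.035 with an estimated correlation), and Hand1 is in both lists. Imprinted genes were higher for 8 of 13, with Peg10 (7.02 ± 0.32) and Phlda2 (6.28 ± 0.27) (adjusted p = 5.5e-05, adjusted p = 0.049 with an estimated correlation). Y-linked genes were higher for 3 of 3, with Eif2s3y (7.03 ± 0.59) (adjusted p = 5.5e-05, adjusted p = 0.031 with an estimated correlation).

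Proliferation genes were higher in region 12 for 13 of 15, with Mcm6 (2.10 ± 0.19) and Mcm5 (2.05 ± 0.14) (adjusted p = 2.3e-06, adjusted p = 0.098 with an estimated correlation). Glycolysis genes were higher for 9 of 16, with Slc2a3 (3.55 ± 0.19) and Eno1 (2.29 ± 0.15) (adjusted p = 1.7e-05, adjusted p = 0.19 with an estimated correlation). Stromal matrix genes were lower for 16 of 18, with Col1a1 (-4.01 ± 0.35) and Timp2 (-3.54 ± 0.31) (adjusted p = 2.5e-07, adjusted p = 0.033 with an estimated correlation). Endothelial genes were lower for 10 of 17, with Eng (-3.08 ± 0.35) and Emcn (-2.22 ± 0.33) (adjusted p = 2.5e-04, adjusted p = 0.13 with an estimated correlation). Col6a2 (at least 81.1-fold), Axl (at least 18.4-fold) and C1qb (at least 19.2-fold) had no counts and were lower by these bounds, against a floor of 3 counts over the group. Without replicate 4, where 1 sum of 117657 UMIs remains for region 12 and is assumed to vary like the other regions, 579 genes were called, against 1809 without the library of replicates 1 and 2, where 1 sum also remains.

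Region 13 (Tnnc1, Htra1, Retn) was led by Klk7 (6.78 ± 0.37), Fbln7 (6.69 ± 0.20), Prl3c1 (6.68 ± 0.23), Crct1 (6.15 ± 0.17) and Prl8a9 (6.04 ± 0.20). Prl3c1 reached 27479 ± 7886 TMM-scaled CPM (SD, n = 2). Decidual markers were higher for 10 of 20, with Prl8a2 (5.10 ± 0.23) and Lifr (4.29 ± 0.17) (adjusted p = 8.0e-04, adjusted p = 0.11 with an estimated correlation). Cholesterol and steroid synthesis genes were higher for 5 of 11, with Sqle (2.87 ± 0.19) and Fdps (2.17 ± 0.16) (adjusted p = 0.0021, adjusted p = 0.035 with an estimated correlation). Trophoblast genes were higher for 6 of 16, with Tpbpa (6.31 ± 0.34), a gene of the ectoplacental cone, and Prl3d1 (3.54 ± 0.41) (adjusted p = 0.040, adjusted p = 0.35 with an estimated correlation), and the list mean turned to -0.026 (adjusted p = 0.93) at a resolution of 0.3.

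Mitochondrially encoded genes were lower in region 13 for 9 of 12, with mt-Cytb (-2.02 ± 0.20) and mt-Co3 (-1.95 ± 0.23) (adjusted p = 4.3e-04, adjusted p = 0.29 with an estimated correlation). Proliferation genes were lower for 13 of 15, with Cdk1 (-2.24 ± 0.45) and Birc5 (-2.09 ± 0.40) and Mki67 (26.2-fold, counting interval 7.25 to 216) (adjusted p = 1.1e-04, adjusted p = 0.18 with an estimated correlation). Col16a1 (at least 35.5-fold), Thy1 (at least 14.4-fold) and Vcan (at least 13.7-fold) had no counts and were lower by these bounds, against the same floor. Region 13 rested on 2 libraries with 20 and 25 spots, and 773 genes were called without replicate 4. It matched the same region as region 7 in 3 of the 6 other clusterings.

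UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which a dam does not carry and a male conceptus does, numbered 29, 38 and 88 in the library of replicates 1 and 2, replicate 3 and replicate 4. Regions 11 and 12 together held 72.4% of them (exact 95% binomial interval 52.8 to 87.3), 84.2% (68.7 to 94.0) and 88.6% (80.1 to 94.4), against 3.48%, 4.34% and 9.07% of all UMIs. These 2 regions were picked for the share after the clustering was seen. In replicate 3 the share is of region 11 alone, since region 12 had no spots there. The intervals take UMIs as independent, although some shared a spot, such as 39 UMIs in 19 spots of region 12 in replicate 4.

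**Figure D3:**
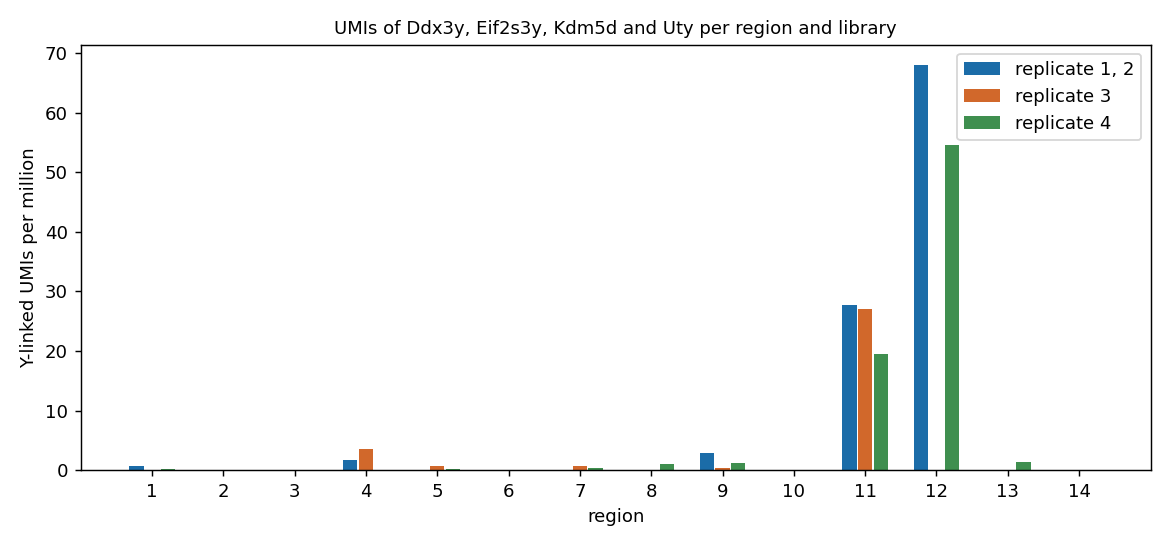
CPM of 4 Y-linked genes summed (vertical axis) in each of the 14 regions, one bar per library. Regions 11 and 12 stood above the other regions in each library that held them.

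**Figure D4:**
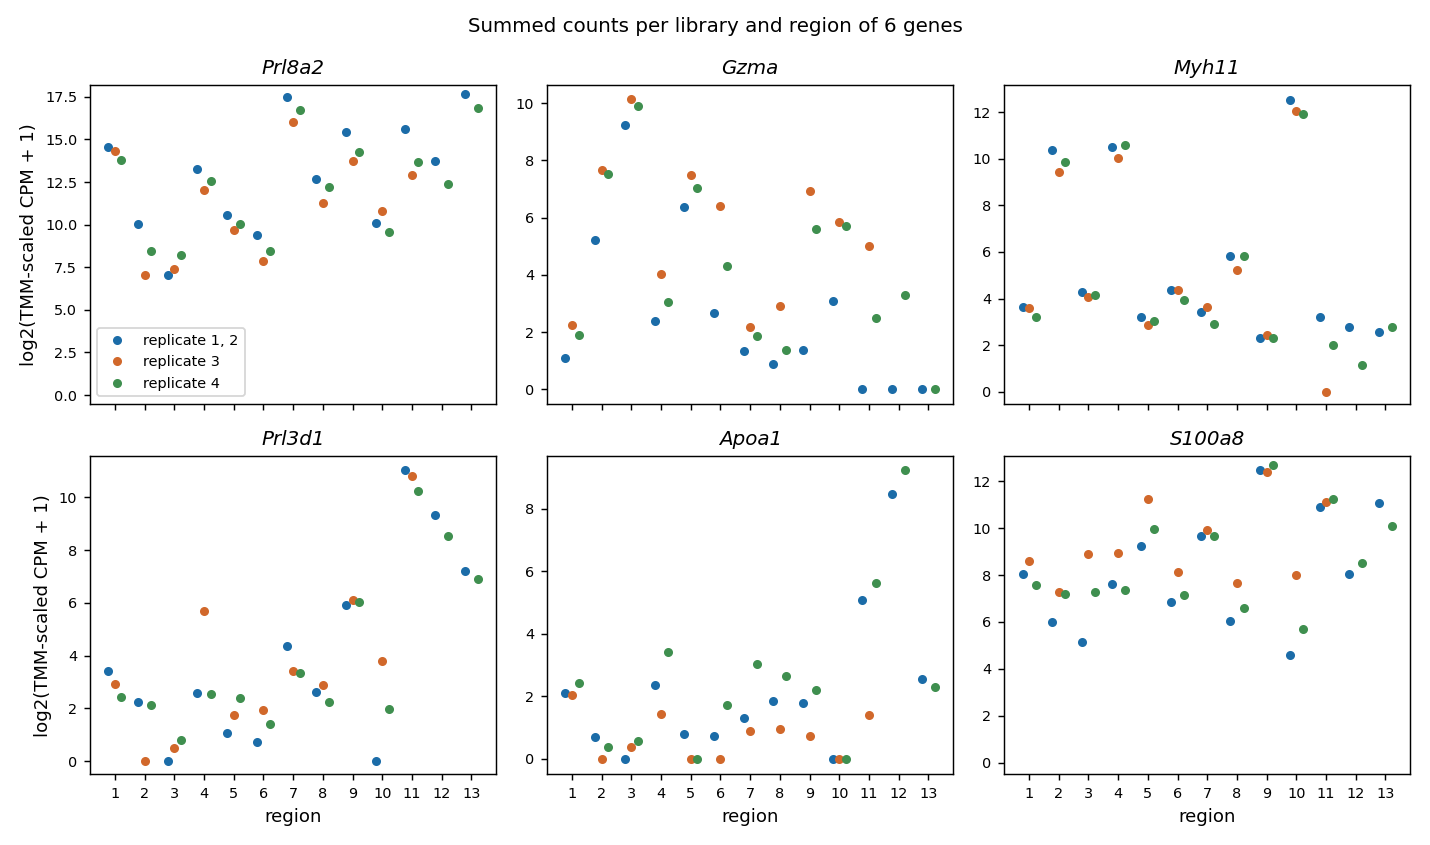
Log2(TMM-scaled CPM + 1) of summed counts for 6 genes, one point per library (colour) and tested region (horizontal axis). Prl8a2 was highest in regions 7 and 13, Gzma in region 3, Myh11 in region 10, Prl3d1 in region 11, Apoa1 in region 12 and S100a8 in region 9.

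The decidual-highest region (region 7) and the natural killer cell-highest region (region 3) were then compared directly, leaving out the genes of the 2 lists that picked them. Of 6653 genes tested, 1067 were higher in region 7 and 1497 in region 3. Region 7 was higher in Gdpd2 (9.56 ± 0.43), Sprr2h (8.79 ± 0.35), Fabp4 (8.73 ± 0.43), Sema3e (8.19 ± 0.34), Lipg (7.74 ± 0.32) and Adamts5 (7.72 ± 0.31), of which Lipg encodes a lipase of the vessel wall and Adamts5 a matrix protease. Fabp4 stood at 10704 ± 3399.6 TMM-scaled CPM (SD, n = 3) in region 7. Proliferation genes were lower in region 7 for 13 of 15, with Mki67 (-3.40 ± 0.24) and Ube2c (-3.36 ± 0.27), and Rrm2 (2.57 ± 0.18) was higher (adjusted p = 1.2e-05, adjusted p = 0.18 with an estimated correlation). Stromal matrix genes were lower for 12 of 18, with Col1a2 (-3.91 ± 0.17) and Mmp2 (-4.22 ± 0.36), whereas Postn (3.42 ± 0.29) was higher (adjusted p = 9.6e-04, adjusted p = 0.18 with an estimated correlation). Macrophage genes were lower for 12 of 15, with Tyrobp (-4.39 ± 0.31) and Fcer1g (-4.18 ± 0.27), 2 signalling adaptors that natural killer cells share, while Csf1r (3.44 ± 0.18) and Cd68 (2.94 ± 0.21) were higher (adjusted p = 0.015, adjusted p = 0.35 with an estimated correlation). Unfolded protein response genes were higher for 4 of 11, with Dnajb9 (3.25 ± 0.17) and Xbp1 (1.70 ± 0.16) (adjusted p = 0.0094, adjusted p = 0.33 with an estimated correlation). Chemokines and cytokines were lower for 6 of 15, with Il15 (-4.82 ± 0.57) and Cxcl14 (-3.42 ± 0.26) (adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). None of the 10 list tests that passed held with an estimated correlation.

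Over all spots, the decidual list took 38699.9, 15253 and 24163 CPM in the library of replicates 1 and 2, replicate 3 and replicate 4, mostly from Prl8a2 and Cryab. Natural killer cell genes took 1407, 8156 and 3338 CPM in the same order, mostly Gzmd and Gzmf. Adult globin genes took 2806, 969.8 and 1988 CPM, smooth muscle genes 5814, 3288 and 4147 CPM and yolk sac and visceral endoderm genes 483, 189 and 653 CPM. The yolk sac list was mostly Spink1 and Rbp4 in counts. It took 1742 ± 566 CPM in region 8 and 1126 ± 403 CPM in region 4 (SD, n = 3), against 6132 ± 703 CPM in region 12 (SD, n = 2). Region 12 had no spots in replicate 3, so these levels do not measure yolk sac alone. Of 35 lists, 8 differed by over 2 times between libraries, 1 of them the embryonic globins. The parietal endoderm list (5759.6 ± 346 CPM, SD, n = 3, mostly Srgn and Sparc), the basement membrane list (2945 ± 78.4 CPM) and the unfolded protein response list (3669 ± 101 CPM) were close between libraries. T and B cell genes took 17.8 ± 4.29 CPM, with 2 members tested, too few for a list test. Embryonic globins had 1 UMI in all and were not detectable at this depth, where a count of 0 allows up to 0.177, 0.110 and 0.100 CPM. Lymphatic endothelium (lowest adjusted p = 0.051, region 4), angiogenic ligands (adjusted p = 0.077, region 10) and the polyploid decidual cell cycle (adjusted p = 0.090, region 6) passed in no region.

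Across spots thinned to 3000 UMIs, natural killer cell and decidual list counts were inversely ranked, with Spearman's rho of -0.52, -0.68 and -0.55 in the library of replicates 1 and 2, replicate 3 and replicate 4. Macrophage and decidual lists gave -0.36, -0.56 and -0.40, and smooth muscle and decidual lists -0.51, -0.32 and -0.40. Proliferation and decidual lists were ranked alike, with 0.47, 0.44 and 0.48, while glycolysis and decidual lists gave -0.30, -0.31 and -0.14. Natural killer cell and endothelium lists gave 0.09, -0.03 and 0.05, and macrophage and endothelium lists 0.06, 0.04 and 0.11. Trophoblast with adult globins gave 0.16, 0.17 and 0.21, trophoblast with Y-linked transcripts 0.09, 0.16 and 0.14, and yolk sac with Y-linked transcripts 0.02, -0.03 and 0.08. Spots are not independent, so no p-value was computed, and 8 of 10 pairs kept 1 sign in all 3 libraries. The list sums follow their most counted members, which for proliferation is Rrm2. Most proliferation genes were lower in regions 7 and 13, where the decidual list was highest (113685 and 159988 CPM in mean). The positive rho thus does not describe most members there. For the macrophage list the most counted were Tyrobp and Fcer1g, which natural killer cells share, and for the yolk sac list Spink1 and Rbp4.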

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

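No test in this part was planned, and the values of region 14 were looked at after the clustering was seen. Region 14 (Fxyd3, Prom1, Scgb3a1) was left out of the comparisons because it had 13 spots, with 4 in the library of replicates 1 and 2, 3 in replicate 3 and 6 in replicate 4. Its spots carried the epithelium list at 92141 CPM, or 15322 of 166288 UMIs, where a count of 0 would allow 18.0 CPM. Most of it came from the gland proteases Prss29 at 66589 CPM and Prss28 at 23237 CPM. The keratins Krt18 at 728 CPM and Krt7 at 385 CPM followed, and then Epcam at 259 CPM. The clustering did not use these genes. The difference from the tested regions was not tested.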

How the results depend on the processing

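Of 312 named gene calls, 1 was lost with DESeq2's Wald test, 1 with DESeq2 size factors, 25 without replicate 4 and 15 against all other spots of the library, where 8 more turned. At a resolution of 0.3 it was 18, at 1.0 it was 7, without a minimum of UMIs 12 and 1 that turned, with at least 5000 UMIs 8 and 1, and with clustering on the other gene set 12 and 2, where some genes that entered that clustering were not tested. The 312 are the calls that the text names, selected while writing from 844. They were drawn from the largest changes and the list members with the smallest p, so their stability says little about all calls. Without a minimum fold change the counts were 2703, 3286, 3235, 2673, 2380, 2473, 2988, 2165, 3183, 2902 and 2840 genes in regions 1 to 11 and 3872 in the direct comparison, because smaller changes enter. Leaving out each library in turn gave 579 to 1919 genes in region 12 and 773 to 1566 in region 13. The lowest values came without replicate 4, where 1 sum remains, and the other case with 1 sum, without replicates 1 and 2, gave 1809 and 1386. The number of lists that differed by over 2 times between libraries was 3 to 6 when a library was left out (3 without replicate 3, 5 without replicate 4) and 3 with the mean of log2(CPM + 1), where the embryonic globins with 1 UMI count in all but the 5 and the last 3. Against all other spots, region 1 had 1480 genes, and these turned: Gzmb and Gzmd in region 2 (-0.054 and -0.31), natural killer cell genes, Prf1, Gzma and Gzmg in region 5 (-0.61, -0.50, -0.54 and -0.21), smooth muscle genes, Myl9 and Acta2 in region 8 (-1.48, -1.06 and -1.46), and trophoblast genes and Prl3d1 in region 9 (-0.36 and -0.40). This contrast is dominated by whichever region holds most of a transcript. Clustering on the other gene set turned natural killer cell genes in region 5 (0.076 in mean with a downward test), Csf1r and Cd68 in region 7 (-0.38 and -0.080), but the matching regions shared only part of the spots of regions 5 and 7 (Jaccard index 0.33 and 0.52). A resolution of 0.3 gave 8 regions and turned proliferation in region 4 (0.22), immediate early genes in region 6 (-0.012 in mean with an upward test), hormone response genes in region 11 (-0.011 in mean with an upward test) and trophoblast in region 13 (-0.026), and a resolution of 1.0 turned natural killer cell genes in region 5 (-0.21). In region 12 Irf7 was at 0.10 without a minimum of UMIs per spot, and at 0.022 with at least 5000 UMIs, where interferon response genes had -0.053 in mean with an upward test. In both settings regions 11 and 12 matched 1 region, so these values are of their spots together. At a resolution of 0.3, region 4 matched the same region as regions 2 and 10 (Jaccard index 0.39), and region 6 the same as region 5 (0.46). Region 11 matched the same region as region 9 (0.33), and region 13 the same as region 7 (0.13). The turned values at that resolution are thus of merged spots. The cause of the other turns was not tested. Over the other clusterings and depths 36 shares of spots moved by over 1 SD and 48 did not, and region 13 matched the same region as region 7 without centring, at a resolution of 0.3 and without a minimum of UMIs. Of the list pairs, trophoblast with Y-linked transcripts went from a mean rho of 0.13 to 0.069 at 1000 UMIs and 0.25 without thinning, proliferation with the decidual list from 0.46 to 0.38 and 0.55, and trophoblast with adult globins from 0.18 to 0.13 without thinning. With an estimated correlation 35 of the 198 list tests passed. Without the replicate block no count moved by over 1.5 times and 312 gene calls stood, with 186 list tests passing. With at least 5000 UMIs per spot, region 10 gave no value. Depth limits region 12 in the library of replicates 1 and 2, where its sum held 117657 UMIs.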

Other observations

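The tests in this part were chosen only after the result was seen, except the tests of the fixed gene lists and their genes, the shuffling of region labels for the list tests and the first count of epiblast transcripts in spots of replicate 3. None of the list tests in this and the next paragraph held with an estimated correlation. In region 12 epithelium genes were higher for 11 of 15, with Epcam (4.55 ± 0.27), Cdh1 (4.34 ± 0.34) and Krt8 (4.31 ± 0.17) (adjusted p = 1.3e-04, adjusted p = 0.086 with an estimated correlation). Interferon response genes were lower there for 7 of 12 (8 adjusted over the list alone), with Irf7 (-3.14 ± 0.38) and Ifi27l2a (-2.72 ± 0.39) (adjusted p = 0.0085, adjusted p = 0.18 with an estimated correlation). With at least 5000 UMIs per spot, where regions 11 and 12 matched 1 region, that list had -0.053 in mean with an upward test (adjusted p = 0.96) and Irf7 turned to 0.022, and without a minimum, where they also did, Irf7 was at 0.10. The neutrophil list was higher in region 11 for 5 of 5, with the chemokine receptor gene Cxcr2 (5.95 ± 0.58) and S100a9 (4.0 ± 0.21) (adjusted p = 6.3e-05, adjusted p = 0.064 with an estimated correlation). In region 13 it was higher for 4 of 5, with the decoy receptor gene Il1r2 (3.19 ± 0.25) and S100a8 (2.43 ± 0.31) (adjusted p = 0.018, adjusted p = 0.22 with an estimated correlation).

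Progesterone and estrogen response genes were higher in region 8 for 5 of 13, with Fst (2.44 ± 0.11), Hoxa10 (1.40 ± 0.09) and Esr1 (1.21 ± 0.14) (adjusted p = 0.0028, adjusted p = 0.064 with an estimated correlation). They were lower in region 11 for 5 of 13, with Esr1 (-2.48 ± 0.26) and Fst (-1.62 ± 0.17), while Cited2 (2.31 ± 0.10) was higher (adjusted p = 0.013, adjusted p = 0.10 with an estimated correlation), and at a resolution of 0.3 the list had -0.011 in mean with an upward test (adjusted p = 0.66). In region 10 cholesterol and steroid synthesis genes were lower for 5 of 11, with Cyp11a1 (-2.06 ± 0.22), and the cholesterol transport gene Star (2.23 ± 0.39) was higher (adjusted p = 0.0055, adjusted p = 0.054 with an estimated correlation). The differences between these regions were not tested.

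Granzyme transcripts were above the mean of the other regions in region 5 although region 3 held far more. Read sharing between Gzmd, Gzme, Gzmf and Gzmg was argued against by the genes outside that group, since the lowest log2 fold change of Gzma, Gzmb and Prf1 in region 5 was 3.24. RNA or cells of region 3 at a lower share stayed open as a candidate explanation. The log2 ratio of the 4 granzymes to the other natural killer cell genes differed between regions 5 and 3 by 0.028 ± 0.079 (SD, n = 3), where a shared source needs a difference near 0. No biological explanation was tested, since the libraries form 1 group.

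S100a8 and S100a9 were high in region 9. Neutrophils as their one source in every region were set against the genes Retnlg, Csf3r, Ly6g, Ngp and Cxcr2. These gave 3, 3 and 25 UMIs in region 9 beside 7542, 17005 and 20797 UMIs of the calprotectin pair. The ratio of the former to the latter was lower in region 9 than in the other regions together by a log2 difference of -3.11 ± 0.66 (SD, n = 3). Cxcr2 was higher in region 11, which carried trophoblast transcripts, and can raise the ratio of the other regions without neutrophils. The genes were not counted apart, so the ratio cannot decide on this explanation. Other cells of region 9 that express the pair may account for its level, which was not tested, and no biological explanation was given by the design.

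Region 12 had no spots in replicate 3. Lower depth of that library was argued against, since its median UMIs per spot were 3.30 times those of the library of replicates 1 and 2, which held region 12. Placement of such spots in other regions by the clustering was argued against as the reason, since 0 spots of replicate 3 reached the lower quartile of region 12 for both the epiblast and the yolk sac list, which 26 of the 52 spots of region 12 did. At the 10th percentile 3 spots of replicate 3 did, all in region 4, where 3 spots of the library of replicates 1 and 2 did too, so a few such spots are not excluded. The planned count gave 13 spots of replicate 3, all in region 11, that reached the region 12 median of 3 UMIs of the epiblast list at equal depth. That count does not part region 12 from trophoblast, since region 11 of the other libraries held 3 of 47 and 10 of 55 such spots. By CPM instead, 6 spots of replicate 3 reached the region 12 median with the whole list and 0 without the trophoblast gene Hand1, and its region 11 had 87.1 CPM of the list against 1249 and 984 CPM in region 12. A section that missed the embryo stayed open and untested.

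Region labels were shuffled within each library, and with the real labels 100 splits were counted. In every tested region 1 of the 100 splits, the real one, called as many genes. The clustering had already grouped like spots of all libraries, so the real labels were favoured from the start. These shuffles therefore cannot decide on chance, and the same holds for the list tests and the direct comparison. The real count and the highest other were 979 and 484 in region 1, 1560 and 790 in region 2, 1322 and 390 in region 3, 1268 and 680 in region 4, 1008 and 225 in region 5, 1021 and 589 in region 6, 1578 and 543 in region 7, 1016 and 251 in region 8, 1335 and 861 in region 9, 1883 and 336 in region 10, 1490 and 659 in region 11, 1918 and 257 in region 12 and 1623 and 548 in region 13. Of the list tests 198 passed with the real labels and up to 150 with shuffled ones, again 1 of 100 splits. Shuffled sums keep the differences between regions, but whether this lets many lists pass with the preset correlation was not tested. As so many passed with shuffled labels, list calls that fail with an estimated correlation are weak evidence for their region. For the direct comparison of regions 7 and 3, 1 of the 10 splits of the 6 sums called as many genes, 2564 against at most 1 in the others, and 10 splits are too few for a share under 0.05.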
